A study of Mus musculus with 26 samples.

How the data were processed

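RNA from the aorta of male mice was sequenced in 26 libraries. Of these, 16 came from untreated mice and form 4 groups of 4: ascending and descending aorta, each from wild-type and Fbn1 C1041G/+ mice. The other 10 came from the ascending aorta of C1041G/+ mice given an antisense oligonucleotide (ASO), 5 with AGT-ASO and 5 with a control ASO. The labels name 1 µg of RNA per library, a fibrous tissue RNA kit and a NEBNext Ultra RNA library kit.

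The deposited files hold raw counts per Ensembl gene, 1 file per library, with no normalization. The values were checked to be whole numbers. They sum to 17171652 to 28554356 counts per library, and 19903 to 22436 genes have at least 1 count. Per the submitters' processing notes, reads were trimmed with fastp and aligned with STAR 2.6.1d to the mouse build mm10. The counting tool, the strand setting and the annotation release are not given in the sources used here. Gene names and coordinates were therefore taken from GENCODE M21, on the same build under its name GRCm38. It names 99.77% of the 54532 identifiers; 123 have no name and 203 share a name with another gene. Because the strand setting is unknown, counts of genes that overlap another gene on the opposite strand carry an added uncertainty.

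Expression is given as CPM, the usual per-library unit, which divides a count by the library's total scaled by its TMM factor. Errors of CPM values are standard deviations (SD) between libraries, and errors of log2 fold changes are standard errors (SE) of the model. At these depths a count of 0 in a group is read against a floor of 3 counts over the group. A ratio against a group with 1 to 3 counts has an exact 95% interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

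The fit used the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM factors, the filterByExpr filter by group and robust dispersion estimates. The 16 untreated libraries were fitted together, with 15645 genes, 12 residual degrees of freedom and a biological coefficient of variation of 15.9%. The 10 antisense libraries were fitted apart, with 14981 genes, 8 degrees of freedom and a coefficient of 17.1%. The 6 comparisons were genotype in each region, region in each genotype, the interaction of genotype and region, and AGT-ASO against control ASO. All tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. On simulated data made from these counts, 2-fold changes were recovered in 55.2% to 77.6% of the genes given one. False calls were 1% to 7.5% of the called genes. The simulated counts were drawn independently, with no variation shared by the regions of 1 mouse or through tissue content. These shares may therefore not hold for the real libraries. In the list test on such data, with 1 list changed, 1 list was called by ascending genotype, 0 of them falsely, but 3 with AGT-ASO, of which 2 were false.

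Before the data were examined, 48 gene lists with 1259 entries were fixed from textbook knowledge; 2 entries matched no gene. They cover vascular pathways, matrix, and markers of other cell types and tissues. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, then again with an estimated correlation and with fry. For each list, members were also adjusted over the list alone. The listed pathways were not chosen on these samples. Marker scores are the mean log2 CPM of a list, and name no cell type in a library.

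The rule for named genes was also fixed beforehand. It takes Agt, Fbn1 and the angiotensin receptor genes in any case. It adds the 10 largest rises and the 10 largest falls among called genes with at least 1 CPM in a compared group and no overlap between the groups' libraries. Unnamed gene models, pseudogenes and receptor segments are left out. Up to 4 members with the smallest p are named from a described list. Chance gives non-overlapping groups for 2.9% of genes with 4 against 4 libraries and 0.8% with 5 against 5. Genes picked outside the rule as results of a comparison are marked as chosen after their values were seen. Marker genes that describe the libraries, such as Myh6, Pecam1 and Acta2, are not marked. Of the genes taken in any case, those removed by the count filter were compared by exact permutation of the libraries' CPM, adjusted over 7 tests, a test chosen after the values were seen. Some genes that the rule takes are not reported here.

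Ascending and descending libraries share the numbers 1 to 8. After the group means were removed, all 8 pairs with the same number correlated across genes at r of 0.162 to 0.305 (genes are not independent replicates). Other pairs had a mean of -0.077, and each of the 8 ascending libraries correlated best with its own number. The numbers were therefore taken to pair the regions of 1 mouse, and were used as a replicate block in alternative fits. For genotype within a region the block was random, with an estimated correlation of 0.269, since each mouse has 1 genotype. Blocked values are printed where they end a named gene's call, change the call of a list or move a count by over 1.5 times. No library was a copy of another: 0 of 44 pairs within groups matched within counting error. The labels give no sequencing batch.

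Alternatives fixed beforehand were RLE factors, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, an adjusted p under 0.01, a 2-fold limit, and the heart muscle or the brown adipocyte score as a covariate. The compared libraries fitted alone, the replicate block, and each library left out in turn were also fixed. Chosen after seeing the data were the mitochondrial share as a covariate and leaving out libraries that stand apart in marker scores or principal components. These were wild-type ascending library 3, mutant ascending library 2, wild-type descending library 1, AGT-ASO library 20 and control ASO library 16. The same holds for the heart muscle score, with all libraries or 1 left out, and the genes called in both regions in the test of ascending genotype genes. It also holds for the block and the heart muscle score in the list tests. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the main fits. Read files and alleles were not analysed here, so the Fbn1 genotype rests on the labels.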

Results

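The 26 libraries measure gene expression in the aorta of male mice that carry, or lack, a mutation of Fbn1. Fbn1 encodes fibrillin-1, the main protein of the microfibrils of elastic tissue, and mice heterozygous for C1041G are a model of Marfan syndrome. The untreated groups, each of 4 mice, had 18613662 to 21741934 counts per library in wild-type ascending aorta and 18534146 to 23959303 in mutant ascending aorta. Wild-type descending aorta had 17171652 to 19717144 and mutant descending aorta 17678343 to 20777613. Of the antisense groups, each of 5 C1041G/+ mice, AGT-ASO had 17355174 to 23544005 and control ASO 17367021 to 28554356. AGT-ASO is an oligonucleotide against the mRNA of angiotensinogen, the precursor of angiotensin II, which is made mainly in the liver.

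Smooth muscle markers had the highest score of the marker lists in every group, while markers of neighbouring tissues differed by region and by group. The smooth muscle score was 9.28 ± 0.18 (SD, n = 4) in wild-type and 9.35 ± 0.16 in mutant ascending aorta, and 9.38 ± 0.12 and 9.43 ± 0.05 in descending aorta, on the log2 CPM scale. The heart muscle score was 3.66 ± 1.25 in wild-type and 2.88 ± 0.89 in mutant ascending aorta, against 0.19 ± 0.17 and 0.18 ± 0.10 in descending aorta. In the antisense experiment it was 3.18 ± 0.69 (n = 5) with AGT-ASO and 4.44 ± 0.60 with control ASO. Myh6, the atrial and adult heart myosin, stood at 125 ± 86.0 CPM in wild-type and 48.3 ± 45.9 CPM in mutant ascending aorta. It stood at 101 ± 56.7 CPM with AGT-ASO and 282 ± 102 CPM with control ASO. The mesothelial score was 4.98 ± 0.22 and 5.11 ± 0.31 in ascending aorta, and 0.07 ± 0.44 and 0.84 ± 0.40 in descending aorta. Mitochondrial genes took 5.02 ± 1.25% of the counts with AGT-ASO and 7.98 ± 2.31% with control ASO, and 2.51 to 4.11% in untreated libraries. The first principal component held 70.6% of the variance of the untreated libraries and 31.0% of that of the antisense libraries.

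The mutated gene and the genes of the angiotensin pathway are the reference points of the design. Fbn1 (GRCm38, chromosome 2, 125300594 to 125507993) stood at 406 ± 89.3 CPM in wild-type and 363 ± 25.0 CPM in mutant ascending aorta, and at 377 ± 50.1 and 418 ± 65.9 CPM in descending aorta. It passed no test by genotype (adjusted p = 0.63 and 0.80), region (0.78 and 0.50) or AGT-ASO (0.75). Agt itself was near the detection limit, with 1 to 28 counts per library, and the count filter removed it. Its mean was 0.399 ± 0.599 CPM (SD, n = 5) with AGT-ASO and 0.484 ± 0.193 CPM with control ASO (exact permutation test of the means, adjusted p = 0.86 over 7 tests). AGT-ASO library 15 had 1.467 CPM; the other 4 had 0.0961 to 0.208 CPM and the control libraries 0.301 to 0.787 CPM (exact permutation test without library 15, unadjusted p = 0.016). Agt stood at 0.0945 ± 0.0275 CPM (SD, n = 4) in wild-type and 0.681 ± 0.545 CPM in mutant descending aorta, where the groups did not overlap (exact permutation test, p = 0.029, the smallest that 4 against 4 libraries can give; adjusted p = 0.20), with mutant library 6 at 1.495 CPM and the other 3 at 0.340 to 0.450 CPM. In ascending aorta it stood at 0.430 ± 0.225 CPM in wild-type and 0.202 ± 0.170 CPM in mutant mice (exact permutation test, adjusted p = 0.60). Agtr2 had 0 to 16 counts per library, was removed as well and passed none of these exact tests (adjusted p = 0.60 for genotype in each region and for AGT-ASO). These permutation tests were chosen after the values were seen. Agtr1a, the main angiotensin II receptor gene of mice, passed no test by genotype (log2 fold change 0.11 in ascending and 0.26 in descending aorta, adjusted p = 0.87 and 0.84). With AGT-ASO its log2 fold change was -0.23 (adjusted p = 0.70). Agtr1b, the second type 1 receptor gene, rose in mutant descending aorta from 1.22 ± 0.31 to 2.92 ± 0.85 CPM (SD, n = 4; log2 fold change 1.26 ± 0.30 SE, adjusted p = 0.0495). That call was lost in 12 of 17 alternatives, 7 of which leave out 1 library each. In ascending aorta Agtr1b had a log2 fold change of 0.32 (adjusted p = 0.72), and in the antisense libraries the count filter removed it (exact permutation test, adjusted p = 0.60).

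The first genotype comparison asks how the ascending aorta of C1041G/+ mice, a site of aneurysm in Marfan syndrome, differs from that of wild-type littermates. Igfbp2, a binding protein of insulin-like growth factors (ENSMUSG00000039323, chromosome 1, 72824503 to 72852474), had the largest rise. It went from 93.2 ± 12.96 to 638 ± 221 CPM (SD, n = 4; log2 fold change 2.77 ± 0.22 SE, adjusted p = 8.9e-06). Esm1, a proteoglycan secreted by endothelial cells, rose from 2.15 ± 0.64 to 10.9 ± 2.19 CPM. The ATP-gated channel gene P2rx1 rose from 22.3 ± 4.58 to 73.7 ± 19.1 CPM, and Sncg from 63.6 ± 16.3 to 217 ± 30.0 CPM. Among the 10 largest rises were also Mogat2, Gcnt4, Nptx2, Gpr176 and Nkx6-1, with log2 fold changes of 1.64 to 2.21. Chad, which encodes the cartilage matrix protein chondroadherin, fell from 47.3 ± 23.1 to 6.29 ± 2.94 CPM (log2 fold change -2.91 ± 0.43, adjusted p = 0.0019). The urotensin receptor gene Uts2r had the largest fall among the genes taken by the rule, with a log2 fold change of -3.40 ± 0.54 from 1.63 ± 0.88 CPM. Pirt, Msc, Gal3st2b, Myh7, Minar1, Atp10b, Igf2 and Tmem35a made up the rest, at -1.82 to -3.03. Gal3st2b belongs to a family of near-identical genes that can share reads. Myh7 is a heart muscle gene, and its group means went the same way as the heart muscle score given above. Its groups did not overlap, which was a condition of the naming rule. The score did overlap, at 4.157 in mutant library 8 and 2.182 in wild-type library 1. Those 2 libraries were therefore ordered otherwise by Myh7 than by the score. Whether Myh7 follows the score library by library was not tested.

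In all, 342 of 15645 genes passed in the ascending aorta, 185 higher and 157 lower in mutant mice. The libraries of the groups did not overlap in 1487 of all tested genes, where chance gives 2.9% of genes, and 325 of these were among the 342. At least a 2-fold change was seen in 108, with 41 higher and 67 lower. The count fell to 163 without mutant library 2, whose thymus score was 1.89 against a group mean of 0.27, and to 206 without mutant library 4. It was 103 without the 3 libraries that stand apart, and 774 with DESeq2. With the heart muscle score as a covariate it was 160. Gpr176 and Myh7 lost their calls in 9 and 11 of 17 alternatives, among them the mouse as a random block (adjusted p = 0.089 and 0.12), and Minar1 lost its call in 12 of 17. Gal3st2b and Igf2 each lost theirs in 7 of 17, of which 4 leave out 1 library, Pirt in 4 (2 that leave out 1 library) and Atp10b in 3 (1, mutant library 4).

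Genes known to respond to angiotensin II had the smallest p of the lists in ascending aorta. Of 19 measured members, 4 rose, none fell and 15 did not pass, while 10 rose when adjusted over the list alone. Among those that rose was Tnc, which encodes the matrix protein tenascin-C (39.6 ± 10.8 to 106 ± 13.6 CPM). So were Ccn2, a connective tissue growth factor (1654 ± 239.6 to 2937 ± 530.1 CPM), and Rcan1, a calcineurin regulator (75.5 ± 18.1 to 169 ± 43.9 CPM). The list's median log2 fold change was 0.83 (adjusted p = 7.8e-11 with the preset and adjusted p = 0.20 with an estimated correlation; fry adjusted p = 0.028). Among 26 targets of transforming growth factor beta, 6 rose and 1, the matrix gene Cilp, fell (8 and 2 adjusted over the list alone), with a median of 0.11; Cilp lost its call without mutant library 2 (adjusted p = 0.053). They shared Tnc and Ccn2 with the first list and included Fn1, which encodes fibronectin (1054 ± 158 to 1995 ± 48.2 CPM, adjusted p = 0.00052). That list had an adjusted p = 5.7e-06 with the preset and adjusted p = 0.45 with an estimated correlation. Of 29 genes of the pathway itself, 3 rose and 1, the latent binding protein gene Ltbp4, fell (6 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.056). Ltbp4 lost its call in 6 of 18 alternatives, 4 of which leave out 1 library each. Members that rose were Lrrc32 (log2 fold change 0.92), Tgfb3 (0.64) and Inhba (0.53).

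Genes of a modulated smooth muscle state moved both ways. Of 30, 6 rose and 1 fell (9 and 4 adjusted over the list alone), with a median of 0.17. Acan, which encodes the proteoglycan aggrecan, rose from 51.9 ± 2.96 to 123 ± 8.48 CPM (adjusted p = 9.4e-07). Igfbp2 and Fn1 are members too, and Chad is the member that fell. The list had an adjusted p = 6.4e-05 with the preset and adjusted p = 0.52 with an estimated correlation. Of 40 contractile genes, 2 rose (4 adjusted over the list alone): the small heat shock gene Hspb1 (533 ± 161 to 1437 ± 214 CPM) and Tagln (log2 fold change 0.40, adjusted p = 0.020). Tagln lost its call in 4 of 8 fits that leave out 1 library, and its position overlaps Pcsk7 on the opposite strand. That list's median was 0.14 (adjusted p = 0.0003 with the preset and adjusted p = 0.57 with an estimated correlation).

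Matrix genes of the elastic fibre list fell in 4 cases of 29 and rose in 1, which was Fbln7, and the list as a whole did not pass (1 and 6 adjusted over the list alone; adjusted p = 0.45). Fbln7 lost its call in 14 of 18 alternatives, among them the mouse as a random block (adjusted p = 0.070). Mfap4 went from 757 ± 120.3 to 463 ± 12.3 CPM and Mfap5 from 313 ± 25.7 to 198 ± 23.5 CPM; both encode proteins that associate with microfibrils. Of 24 genes of fibrillar collagens and their processing, none rose and 2, Pcolce2 and Col11a2, fell, also adjusted over the list alone (adjusted p of the list = 0.78). Col11a2 lost its call in 12 of 18 alternatives, among them the mouse as a random block (adjusted p = 0.061). Of 32 inflammation genes, 2 rose and 30 did not pass, with 6 higher adjusted over the list alone. Osmr, a cytokine receptor gene, rose by a log2 fold change of 0.55 and the chemokine gene Ccl12 by 1.31; Ccl12 lost its call in 8 of 17 alternatives, 5 of which leave out 1 library each. The list's median was 0.59 (adjusted p = 8.7e-07 with the preset and adjusted p = 0.53 with an estimated correlation). Of 30 immediate early and heat shock genes 2 rose, Hspb1 and Hsp90aa1, with 5 higher adjusted over the list alone and a median of 0.38 (adjusted p = 1.1e-05 with the preset and adjusted p = 0.53 with an estimated correlation). Hsp90aa1 lost its call in 9 of 18 alternatives, 6 of which leave out 1 library each. None of 38 interferon response genes passed, with 0 adjusted over the list alone and a median of 0.33 (adjusted p = 0.00014 with the preset and adjusted p = 0.63 with an estimated correlation). None of 36 cell cycle genes passed, with 1 adjusted over the list alone. Their median was 0.62 (adjusted p = 1e-06 with the preset and adjusted p = 0.57 with an estimated correlation). None of 20 macrophage markers passed either, with 1 adjusted over the list alone and a median of 0.36. That list had an adjusted p = 2.9e-05 with the preset and adjusted p = 0.57 with an estimated correlation. Lymphocyte markers had a median of 0.73, with 0 of 20 members adjusted over the list alone (adjusted p = 0.026 with the preset and 0.76 with an estimated correlation). Their score was highest in mutant library 2 (1.587), and the adjusted p was 0.708 without that library, and 0.0887 and 0.087 without wild-type libraries 5 and 7. Neutrophil and mast cell markers had a median of 0.71, with 0 of 15 adjusted over the list alone (adjusted p = 0.036 with the preset and 0.73 with an estimated correlation). That list did not pass without wild-type library 1 or 5 or mutant library 4 or 6 (adjusted p = 0.055 to 0.147), or with the mouse as a random block (0.068).

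Markers of cartilage, heart muscle and brown adipocytes had negative medians in ascending aorta, mutant over wild type, while mesothelial markers had a median of 0.11 and did not pass (adjusted p = 0.32). The cartilage score was 2.27 ± 0.69 in wild-type and 1.21 ± 0.45 in mutant mice. Of 14 cartilage markers, 1 rose, which was Acan, and 2 fell, Chad and Col11a2 (1 and 5 adjusted over the list alone; median -1.22). The list's adjusted p = 0.0049 with the preset and adjusted p = 0.57 with an estimated correlation. None of 21 heart muscle markers passed, alone or over all genes, with 0 adjusted over the list alone and a median of -0.86 (adjusted p = 0.0012 with the preset and adjusted p = 0.63 with an estimated correlation). None of 15 brown adipocyte markers passed over all genes and 1 was lower adjusted over the list alone, with a median of -0.80 (adjusted p = 0.0028 with the preset and adjusted p = 0.57 with an estimated correlation). In all, 16 lists passed at the preset correlation, 13 up and 3 down, and none with an estimated correlation.

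The second comparison asks the same of the descending aorta. Kcnj15, an inward-rectifier potassium channel gene (ENSMUSG00000062609, chromosome 16, 95257558 to 95300260), fell from 45.2 ± 13.4 to 0.859 ± 0.111 CPM (SD, n = 4). Its log2 fold change of -5.71 ± 0.22 SE (adjusted p = 7.9e-11) left 1.9% of the wild-type level. Galnt6, which adds sugars to proteins, fell from 14.1 ± 6.51 to 2.04 ± 0.56 CPM. Angptl7 fell from 37.8 ± 14.8 to 7.37 ± 2.88 CPM. Lmntd1, Frmpd4, Vtcn1, Ffar4, Cacna2d3, Faim2 and Ppp1r1b completed the 10 largest falls, at -1.70 to -3.42. Grem1, which encodes a secreted antagonist of bone morphogenetic proteins (BMPs), had the largest rise of those taken by the rule. It went from 0.081 ± 0.070 to 2.34 ± 1.10 CPM (log2 fold change 4.75 ± 0.71, adjusted p = 0.0013). The guidance factor Sema3e rose from 6.14 ± 0.69 to 27.0 ± 4.25 CPM, Rgs17 from 6.23 ± 3.54 to 26.0 ± 3.55 CPM and Igfbp2 from 13.1 ± 2.81 to 59.4 ± 10.1 CPM. Gcnt4 rose from 1.30 ± 0.11 to 6.61 ± 1.35 CPM. Olfr558, Tmem215, Gpr176, Ak5 and Sphkap were the others, at 1.95 to 2.80; Olfr558 belongs to a large family of similar receptor genes.

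In the descending aorta 189 genes passed, 106 higher and 83 lower in mutant mice, and 186 of them were among the 1141 tested genes whose groups did not overlap. At least a 2-fold change was seen in 95, of which 51 were higher and 44 lower, and DESeq2 called 408. Lmntd1 and Ffar4 lost their calls in 6 and 12 of 17 alternatives, among them the mouse as a random block (adjusted p = 0.065 and 0.051). Sphkap lost its call in 10 of 18 alternatives.

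BMP pathway genes rose in 3 of 23 cases and fell in 1, the receptor gene Bmpr1b (5 and 1 adjusted over the list alone). Bmpr1b lost its call in 7 of 18 alternatives, 4 of which leave out 1 library each. The risers were the antagonists Grem1 and Chrdl1 (36.2 ± 6.87 to 78.7 ± 8.75 CPM) and Fst, which encodes the activin-binding follistatin (7.61 ± 1.63 to 16.6 ± 3.64 CPM). The list had a median of 0.03 and a mean of 0.36 (adjusted p = 0.0053 with the preset and adjusted p = 0.43 with an estimated correlation). In the modulated smooth muscle list 5 of 30 rose and 1 fell (7 and 5 adjusted over the list alone). Acan rose from 25.1 ± 3.21 to 59.3 ± 4.4 CPM and Tnfrsf11b, the osteoprotegerin gene, from 18.95 ± 4.63 to 53.2 ± 10.6 CPM. That list's adjusted p = 3.7e-05 with the preset and adjusted p = 0.43 with an estimated correlation. Of 40 matrix glycoprotein genes 3 rose and 1 fell (5 and 2 adjusted over the list alone), among them Ccn3, from 1101 ± 96.4 to 2197 ± 161 CPM. Its adjusted p = 0.0055 with the preset and adjusted p = 0.67 with an estimated correlation. In the elastic fibre list none rose and 2 of 29 fell (2 and 3 adjusted over the list alone). Mfap4 fell from 564 ± 65.8 to 224 ± 18.5 CPM, and Mfap5 had a log2 fold change of -0.53. The list had an adjusted p = 0.033 with the preset, 0.105 with the mouse as a random block and adjusted p = 0.68 with an estimated correlation. Of 24 genes of fibrillar collagens and their processing none passed, with 1 lower adjusted over the list alone.

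None of 19 angiotensin II response genes passed in the descending aorta over all genes, and 4 rose adjusted over the list alone. Tnc had a log2 fold change of 0.56 (adjusted p = 0.13). The list's median was 0.33 (adjusted p = 0.00023 with the preset and adjusted p = 0.43 with an estimated correlation). Of 11 mesothelial markers 1 rose in mutant descending aorta, which was Gpm6a, and 3 adjusted over the list alone, with a median of 0.74. Gpm6a lost its call in 10 of 18 alternatives, the random block among them (adjusted p = 0.051). That list had an adjusted p = 2.9e-07 with the preset and adjusted p = 0.43 with an estimated correlation. Heart muscle and brown adipocyte markers did not pass (adjusted p = 0.74 and 0.11), with 0 members adjusted over the list alone. Macrophage markers had a median of 0.32, with 0 of 20 adjusted over the list alone (adjusted p = 6.5e-05 with the preset, 0.0518 without wild-type library 5 and 0.65 with an estimated correlation). Erythroid markers had a median of -1.23, with 0 of 9 adjusted over the list alone (adjusted p = 0.00024 with the preset and 0.65 with an estimated correlation), and hemoglobin genes took 0.150 ± 0.058% of the counts in wild-type and 0.062 ± 0.047% in mutant descending aorta. Endothelial markers had a median of -0.25, with 1 of 19 higher adjusted over the list alone, and skeletal muscle markers one of -0.68, with 1 of 12 lower. Their adjusted p was 0.0070 and 0.012 with the preset, 0.181 and 0.199 without wild-type library 1, and 0.67 and 0.65 with an estimated correlation. Genes of oxidative phosphorylation had a median of -0.10, with 0 of 35 adjusted over the list alone (adjusted p = 8.6e-05 with the preset and 0.65 with an estimated correlation). The mitochondrial share of the counts was 3.45 to 3.92% in wild-type and 2.86 to 3.31% in mutant descending libraries. In all, 18 lists passed at the preset correlation, 12 up and 6 down, and none with an estimated correlation.

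The genotype differences of the regions were set against each other. Of the genes called in either region, 83 were called in both, 43 higher and 40 lower in mutant mice, and 0 in opposite directions. Chance would give 1.25 and 0.83 if the regions were independent. Of the 342 genes of the ascending aorta, 321 had the same sign in the descending aorta (93.9%). Both regions came from the same 8 mice, so this overlap is not independent evidence. Igfbp2, Gcnt4, Gpr176, P2rx1 and Acan were higher in both regions, and Kcnj15, Mfap4, Mfap5, Rgs5 and Ptgfr lower in both. Rgs5, a regulator of G protein signalling in mural cells, fell from 222 ± 7.42 to 87.4 ± 19.1 CPM in ascending and from 1109 ± 187 to 550.2 ± 51.2 CPM in descending aorta. Ptgfr, the prostaglandin F receptor gene, had log2 fold changes of -1.74 and -1.51. Rgs5 and Ptgfr were chosen after their values were seen.

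**Figure D1:**
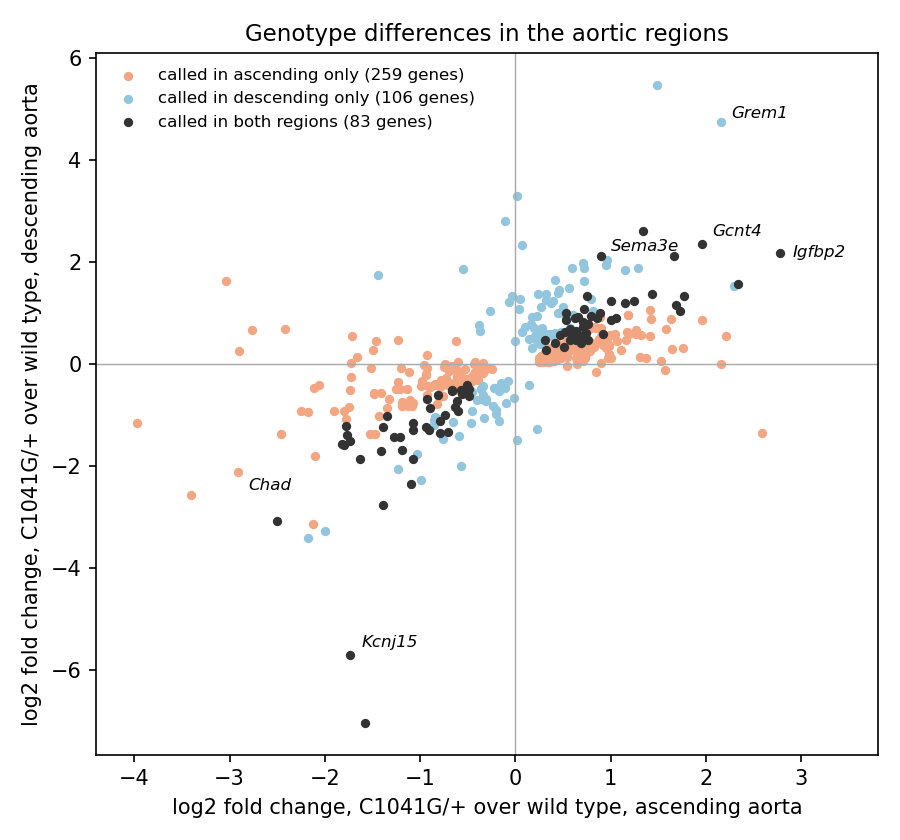
Log2 fold change of mutant over wild-type mice in the ascending (horizontal) and descending aorta (vertical), 1 point per gene called in at least 1 region. The 83 genes called in both regions lie in the quadrants of equal sign, 43 higher and 40 lower, with Kcnj15 at -1.74 and -5.71.

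The interaction of genotype and region asks whether the genotype effect differs between the regions, and Kcnj15 was the only gene called by the unblocked fit. It fell to 29.9% of the wild-type level in ascending aorta (180 ± 16.3 to 54.0 ± 2.88 CPM) and to 1.9% in descending aorta. The difference of the log2 fold changes was 3.97 ± 0.27 SE (adjusted p = 8.2e-07), and its groups did not overlap in either region. The genes next in order did not pass: Msc at -3.11 and Siglecg at 3.94 (adjusted p = 0.051 for both). At an unadjusted p under 0.05 the edgeR count was 795 of 15645 genes (5.08%). That fit treats the regions of a mouse as independent, though their libraries correlated. The share can therefore not be read against the one that chance gives. DESeq2 called 33 genes. With the mouse as a replicate block 13 genes passed. Besides Kcnj15 they included Tnfrsf11b (-0.91, adjusted p = 0.0015) and the endothelin receptor gene Ednra (-1.46, adjusted p = 0.0064). They also included Sema3e (-1.22), Lox, the collagen and elastin crosslinking enzyme gene (0.61), and Tnc (0.89). The others were Serpini1, Sdk2, Cilp2, P2rx1, Hmcn1, Rgs17 and Cyp4b1. In the antisense experiment, where all mice carry the mutation, Kcnj15 stood at 40.3 to 88.9 CPM, with a log2 fold change of 0.30 for AGT-ASO (adjusted p = 0.60).

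**Figure D2:**
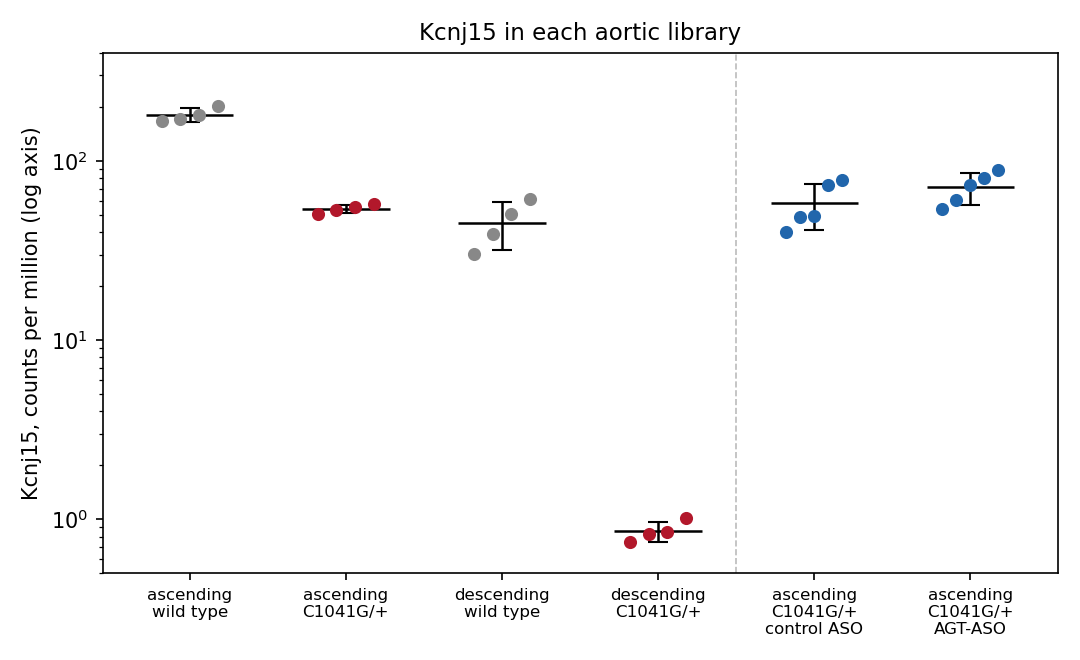
Kcnj15 in CPM on a log axis, 1 point per library, with group means and SD as bars, for the 4 untreated groups (n = 4) and the antisense groups (n = 5). The mutant descending libraries have a mean of 0.859 CPM, against 45.2 CPM in wild-type descending aorta.

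The regions differed far more than the genotypes, and genes that mark position were called in both genotypes. Of 23 Hox genes, which mark position along the body axis, 18 were lower in ascending aorta in wild-type and in mutant mice (18 and 19 adjusted over the list alone, with 1 higher in each). Hoxb8 was at least 507-fold lower in wild-type ascending than descending aorta, Hoxb9 at least 196-fold, and Hoxb7 1796-fold (95% interval 322 to 70968). Hoxa7 stood at 0.309 ± 0.222 CPM in ascending and 36.4 ± 3.53 CPM in descending aorta of wild-type mice. In mutant mice Hoxb6 was at least 799-fold lower and Hoxb8 at least 382-fold lower in ascending aorta. The list's median was -4.96 in wild-type and -5.39 in mutant mice, the same with genes at 0 set to their bound, and its adjusted p = 1.7e-06 and 1.1e-06 with an estimated correlation. Of 32 transcription factors of the outflow tract and heart fields, 16 were higher and 6 lower in ascending aorta of wild-type mice, and 14 and 7 in mutant mice (16 and 9, and 15 and 9, adjusted over the list alone). Gata4 stood at 48.0 ± 13.3 against 0.175 ± 0.078 CPM and Hand2 at 57.5 ± 12.3 against 0.795 ± 0.396 CPM in wild-type mice. That list's adjusted p = 0.00059 and 0.0013 with an estimated correlation. All 11 mesothelial markers were higher in ascending aorta in both genotypes, also adjusted over the list alone, with medians of 5.23 and 4.43. Upk3b stood at 163 ± 28.9 against 3.03 ± 0.71 CPM and Wt1 at 12.7 ± 2.67 against 0.267 ± 0.108 CPM in wild-type mice (adjusted p of the list = 3.7e-05 and 8.8e-05 with an estimated correlation).

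Heart muscle markers were higher in ascending aorta for 15 of 21 genes in wild-type and 10 in mutant mice, and for 16 and 15 adjusted over the list alone (adjusted p = 0.18 and 0.36 with an estimated correlation). Among the largest rises, Clec3a was at least 606-fold higher in wild-type ascending aorta, the heart muscle gene Csrp3 at least 271-fold, the pigment enzyme gene Dct at least 207-fold and Chrm2 at least 131-fold. Of 15 brown adipocyte markers 1 was higher and 1 lower in wild-type mice, and 1 and 4 in mutant mice (1 and 3, and 1 and 4, adjusted over the list alone; adjusted p = 0.92 and 0.82 with an estimated correlation). Ren1, which encodes renin, stood at 18.9 ± 7.56 against 0.396 ± 0.231 CPM in wild-type mice. Agtr1a was higher in ascending aorta (3.53 ± 1.07 against 1.71 ± 0.32 CPM in wild-type mice, adjusted p = 0.016, and 3.82 ± 0.91 against 2.04 ± 0.58 CPM in mutant mice, adjusted p = 0.039). Those calls were lost in 3 and 10 of 18 alternatives, of which 2 and 6 leave out 1 library each. Agtr1b was lower there (log2 fold change -1.66 in wild-type and -2.60 in mutant mice). The adrenergic receptor gene Adra2a was lower in ascending aorta, at 0.983 ± 0.437 against 33.4 ± 6.86 CPM in wild-type mice. Rgs5 had log2 fold changes of -2.32 and -2.65, and Tnc of -1.61 and -0.75. Igfbp2 was higher in ascending aorta (2.83 and 3.42). Ren1, Adra2a, Rgs5, Tnc and Igfbp2 were chosen after their values were seen.

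In wild-type mice 1741 genes passed between regions, 1223 higher and 518 lower in ascending aorta, and in mutant mice 1552, with 1003 and 549. Of these, 1080 were called in both genotypes, 759 higher, 320 lower and 1, Msc, in opposite directions (log2 fold change 1.65 and -1.46, the latter call lost in 6 of 16 alternatives), where chance gives 78.4 and 18.2. At the preset correlation 13 and 16 lists passed. The lists of Hox genes, outflow tract factors and mesothelial markers were the 3 that passed with an estimated correlation in each genotype. With the heart muscle score as a covariate, 313 and 440 genes passed. The score separates the regions, so that fit has little left to compare.

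The antisense comparison asks what changes in the ascending aorta of C1041G/+ mice when the synthesis of angiotensinogen is inhibited. Trem2, a receptor gene of macrophages, rose from 5.48 ± 0.85 to 11.6 ± 2.74 CPM (SD, n = 5; log2 fold change 1.09 ± 0.18 SE). Mgl2, a lectin gene of other macrophages with a close paralog, fell from 6.24 ± 1.48 to 2.43 ± 0.64 CPM (-1.36 ± 0.23). Adamtsl2, which encodes a protein that binds microfibrils, fell from 60.4 ± 10.6 to 34.9 ± 5.17 CPM (-0.79 ± 0.13). Vegfa, a growth factor gene of vessels, fell from 34.2 ± 2.59 to 23.7 ± 2.49 CPM, and Cp, the ceruloplasmin gene, from 142 ± 13.4 to 98.6 ± 10.7 CPM. Dock9, Tspan9, Spry4 and Sorbs2 fell by 0.69, 0.48, 0.48 and 0.41 on the log2 scale. These 9 genes and the unnamed model Gm830, named after its values were seen, were the 10 that passed, 2 higher and 8 lower. Their adjusted p was 0.038, and 0.044 for Sorbs2.

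The 10 calls depended on few libraries and on the test. Of 14981 genes, 1906 had an unadjusted p under 0.05, DESeq2 called 251 and limma-voom 0, with 1967 at an unadjusted p under 0.05. Leaving out 1 library gave 0 calls for AGT-ASO libraries 15, 18 and 19 and control libraries 12, 13 and 16, and 1 for control 17. The count was 40 without AGT-ASO library 14 and 180 without control 8. Heart muscle content differed with treatment as given above; with its score as a covariate 1 gene passed, which was not among the 10. With the brown adipocyte score 0 passed, and with the mitochondrial share 2.

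Heart muscle markers had the smallest p of the lists with AGT-ASO. None of 21 passed over all genes, and 14 were lower and 1 higher adjusted over the list alone, with a median of -1.50 (adjusted p = 2.2e-14 with the preset and adjusted p = 0.38 with an estimated correlation). Tnnt2, a heart troponin gene, stood at 209 ± 34.1 CPM with AGT-ASO and 403 ± 138 CPM with control ASO (adjusted p = 0.21). None of 18 angiotensin II response genes passed, with 1 lower adjusted over the list alone and a median of -0.33 (adjusted p = 0.0004 with the preset and adjusted p = 0.38 with an estimated correlation). Col8a1 had a log2 fold change of -0.49 (adjusted p = 0.15), Ccn2 of -1.09 (0.34) and Rcan1 of -0.57 (0.36). Control library 8 was far above the others for Ccn2 and Rcan1. Of 29 modulated smooth muscle genes none passed, with 1 higher and 5 lower adjusted over the list alone and a median of -0.25 (adjusted p = 0.00028 with the preset and adjusted p = 0.38 with an estimated correlation). Of 28 inflammation genes none passed, with 1 and 4 adjusted over the list alone and a median of -0.28 (adjusted p = 0.00056 with the preset and adjusted p = 0.46 with an estimated correlation).

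Of 19 macrophage markers, 1 rose, which was Trem2 (4 higher and 2 lower adjusted over the list alone; median 0.18; adjusted p = 0.022 with the preset and adjusted p = 0.69 with an estimated correlation). Cd68, a lysosomal macrophage gene, stood at 17.97 ± 4.86 CPM with AGT-ASO and 8.80 ± 2.01 CPM with control ASO (adjusted p = 0.10). None of 40 contractile genes passed, with 0 adjusted over the list alone, and their median was 0.10 (adjusted p = 0.0024 with the preset and adjusted p = 0.69 with an estimated correlation). That list turned downwards with the heart muscle score as a covariate (adjusted p = 0.023). None of 11 brown adipocyte markers passed, with 1 lower adjusted over the list alone and a median of -0.28 (adjusted p = 0.018 with the preset and adjusted p = 0.38 with an estimated correlation). In all, 20 lists passed at the preset correlation, 4 up and 16 down, and none with an estimated correlation.

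The last test asks whether genes that differ by genotype in the ascending aorta move the other way with AGT-ASO, using separate mice. The 184 genes that were higher in mutant mice had a median log2 fold change of -0.13 with AGT-ASO, and 133 of them (72.3%) were lower. As a set they did not pass in one direction (fry, adjusted p = 0.19 over both sets), and passed for change in either direction (adjusted p = 0.013). The 151 genes that were lower in mutant mice had a median of 0.06, with 90 (59.6%) higher (adjusted p = 0.19, and adjusted p = 0.013 in either direction). Both tests therefore failed for a shift in one direction. Change in either direction did not pass without AGT-ASO library 19 or control library 12 (adjusted p = 0.058 and 0.052 for both sets), for the genes that were higher without AGT-ASO library 15 (0.052), or for those that were lower without the libraries that stand apart (0.064). With the heart muscle score as a covariate, an alternative chosen after seeing the data, the medians were -0.23 and 0.20 and both sets passed (adjusted p = 0.0069 and 0.0059). Igfbp2 had a log2 fold change of -0.79 with AGT-ASO (adjusted p = 0.21) and Acan of -0.56 (adjusted p = 0.14). Of 335 ascending genotype genes tested in both experiments, 3 were among the 10 called with AGT-ASO, 1 lower in both (Dock9) and 2 in opposite directions (Sorbs2 and Gm830; Fisher's exact test for the overlap, p = 0.0012). The genotype call of Dock9 was lost in 11 of 18 alternatives, among them all 8 that leave out 1 library, and that of Gm830 in 6 of 18, of which 3 do; their AGT-ASO calls were lost in 14 and 12 of 19, so the overlap rests on unstable calls.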

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

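Of the tests in this part, those of Kcnj15, the heart muscle and mitochondrial covariates of the antisense calls, and the heart muscle and lymphoid tests of the ascending calls were chosen after the results were seen. The same holds for the heart muscle test of the exchange of 2 antisense libraries. The splits of the libraries and the exchange itself were set out before their values were seen.

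Kcnj15 is the gene whose genotype effect differed most clearly between regions, by 3.968 on the log2 scale. No other gene with at least 5 CPM in wild-type descending aorta fell by 50% or more of its log2 fall (0 genes). This argues only against loss of a cell type with many such genes. Galnt6 came close to that limit, at -2.77 from 14.1 CPM. Below 5 CPM, Lmntd1 (-3.42) and Frmpd4 (-3.28) passed it. Genes shared with other cells would fall less, so loss of a cell type with few genes of its own stays open. Reads moving to the overlapping antisense gene are argued against by the summed CPM of both genes, 1.866% of the wild-type sum. A heterozygous variant beside the gene would leave the other allele, and 1.9% of the wild-type level was left, less than 1 allele gives. A homozygous difference that travels with the mutant mice, or an effect of the mutation in trans, stays open and was not tested; 1 of 35 splits, the real one, called a gene in the interaction, and 0 was the highest of the others.

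The 10 genes called with AGT-ASO could reflect the lower heart muscle content of those libraries. With the heart muscle score as a covariate a median of 74.1% of the log2 fold change was kept (quartiles 65.1 to 109%), and with the mitochondrial share 88.56% (79.5 to 97.7%), so neither accounts for the whole change. All 10 calls ended in both fits, where the standard error of each gene was wider: its median went from 0.0994 to 0.140 with the score and 0.116 with the share. With the score Trem2 went from 1.09 ± 0.18 (SE) to 1.47 ± 0.24, and Adamtsl2 from -0.79 ± 0.13 to -0.57 ± 0.18. Of 100 splits drawn, 4 gave as many genes, the real one included, which is under the limit of 0.05. The others gave more than the real one (15, 27 and 211 genes), and the 10 calls depended on few libraries. Chance is therefore not firmly excluded. The highest other, with 211, exchanges AGT-ASO library 14 and control library 8. With the heart muscle score it called 2 genes, but a median of 84.39% of the log2 fold change of the 211 was kept (quartiles 76.2 to 95.7%), which argues against heart muscle content as the whole source of these calls. A swap of these labels cannot be told apart, since 1 of the 2 held-out libraries lay past the midpoint (0.690 for control 8, 0.509 for AGT-ASO 14, on a scale from 0 at the control mean to 1).

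The 342 genes called in the ascending aorta go with a lower heart muscle score and a high thymus score in mutant library 2. Heart muscle content is argued against as the whole cause, since a median of 95.7% of the log2 fold change was kept with its score as a covariate (quartiles 90.8 to 101%). The median of 21 heart muscle markers went from -0.857 to -0.117. These markers make up the score, so their fall follows from the fit and is no separate evidence. Lymphoid tissue in mutant library 2 is argued against as the whole cause, since a median of 94.5% of the log2 fold change was kept without it. Of the 342 genes 157 were still called in each case, and the folds stayed near their size. The standard errors were wider for 320 genes with the score (median 0.146 before and 0.158 after) and for 294 without library 2 (0.149 after). Only the real split of 35 gave as many genes, and 19 was the highest of the others. This argues against chance, but 1 of 35 is the smallest share that this test can give. That share was not adjusted over the comparisons, so chance is not firmly excluded. The genotype itself stays open as the biological explanation. Cartilage content stays open beside it, since its score was 2.273 in wild-type and 1.205 in mutant ascending aorta and was not tested as a covariate.

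A library stood apart from the rest of its group in 30 of 399 groups tested (7.52%), where chance gives about 1 in 20. Control ASO library 8 was high for Ccn2 at 4070 and Rcan1 at 129.4 CPM. AGT-ASO library 14 had a mesothelial score of 5.381, and AGT-ASO library 20 a macrophage score of 2.798 and Cd68 at 9.558 CPM. AGT-ASO library 15 had Agt at 1.467 CPM, AGT-ASO library 18 Agtr2 at 0.4913 CPM and mutant descending library 6 Agt at 1.495 CPM. Control ASO library 16 had Sorbs2 at 324.9 CPM. Smooth muscle scores were low in wild-type ascending library 3 at 9.017 and mutant ascending library 2 at 9.113. The cartilage score was low in mutant ascending library 4 at 0.5267. In wild-type ascending aorta library 1 had Gpr176 at 0.4801 and Hoxb7 at 0.05335 CPM, library 3 Nkx6-1 at 1.06 and Siglecg at 0.1766 CPM, and library 5 Adra2a at 1.631 CPM. In mutant ascending aorta library 2 had Myh7 at 0.4271 and Lox at 718.5 CPM, library 4 Hoxb7 at 0.0544 CPM, and library 6 Agtr1b at 0.6549 and Ren1 at 24.83 CPM. In mutant descending aorta library 2 had Lox at 510.9, Ptgfr at 6.24, Angptl7 at 11.64, Gata4 at 0.3373 and Cyp4b1 at 17.15 CPM. Library 4 of that group had Hoxb6 at 35.02 and Wt1 at 0.17 CPM. Wild-type descending library 5 had Upk3b at 1.981 CPM. Hoxb7 had 1 count in all over the wild-type and 1 over the mutant ascending libraries, so 1 library had to stand apart. Siglecg, Gata4 and Wt1 were also under 1 CPM in the groups named here, where few counts decide.

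With the mouse as a block the genotype effect also differed between regions, ascending minus descending on the log2 scale, for 12 other genes. The difference was positive for Serpini1 (0.659), P2rx1 (0.6836), Lox (0.6124) and Tnc (0.8913). The difference was negative for Tnfrsf11b (-0.9149), Ednra (-1.461), Sdk2 (-1.666), Cilp2 (-1.41), Sema3e (-1.215), Hmcn1 (-1.973), Rgs17 (-1.155) and Cyp4b1 (-1.122). Cilp2 fell mainly in ascending aorta, from 19.6 to 6.87 CPM, against 10.1 to 9.61 CPM in descending aorta. The means of Ednra, Sdk2, Hmcn1 and Cyp4b1 were lower in mutant ascending and higher in mutant descending aorta, and those of Lox the reverse. In the unblocked fit these 12 did not pass.

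At the preset correlation 21 lists differed between regions in the same way, and none with an estimated correlation. Median differences were positive for genes of the angiotensin II response (0.5046), targets of transforming growth factor beta (0.102), inflammation (0.4988), cell cycle (0.3117), oxidative phosphorylation (0.09923), glycolysis and hypoxia (0.1275) and oxidative stress (0.1606). The same holds for markers of lymphocytes (0.7307), neutrophils and mast cells (0.626), skeletal muscle (0.4258) and erythroid cells (0.4897). They were negative for BMP signalling (-0.1652), other collagens (-0.2602), smooth muscle channels and receptors (-0.1003), Wnt and Notch genes (-0.2027) and outflow tract factors (-0.2055). Markers of fibroblasts (-0.1146), heart muscle (-0.5711), Schwann cells and neurons (-0.5714), mesothelium (-0.6219) and cartilage (-0.8502) were negative too. Of 35 splits, 2 gave as many lists, and the highest other gave 26, so chance cannot be excluded for this number.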

How the results depend on the processing

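The libraries that stand apart left out, the mitochondrial share, the genes called in both regions, and the heart muscle score in the list and set tests (in the set tests also with 1 library left out) were chosen after seeing the data. There were 10167 values under the alternatives for the genes taken by the naming rule or named in the text. Of these, 9421 kept their status as called or not called, 536 lost the call and 210 gained one. With a call in either fit, 0 reversed. A change of sign with no call in either fit was counted as kept. Of 1560 for called lists, 1215 kept the call and 343 lost it, which includes any that changed direction without passing. The other 2 reversed and passed in the antisense comparison with the heart muscle score: contractile genes turned lower (adjusted p = 0.0234) and endothelial markers higher (adjusted p = 0.00359). Causes were not tested, except that stricter thresholds and filters leave fewer genes and left-out libraries fewer samples. For ascending genotype (342 genes) the count was 129 at an adjusted p under 0.01, 108 with a 2-fold limit, 774 with DESeq2, 160 with the heart muscle score and 103 without the libraries that stand apart. It was 163 (mutant 2) to 347 leaving out 1 library, and 206 for mutant 4. For descending genotype (189) it was 93, 95 and 408 in the first 3, and 128 to 170 leaving out 1 library. For regions it was 1128 in wild-type and 918 in mutant mice under 0.01, 971 and 868 with the limit, 1037 and 927 with the stricter filter, and 313 and 440 with the heart muscle score. In mutant mice it was 1008 with the brown adipocyte score. The range leaving out 1 library was 1409 to 1782 and 1247 to 1425. For the interaction (1) it was 33 with DESeq2, 2 with limma-voom, 6 with no filter, 2 with the heart muscle score, 2 without the libraries that stand apart and 13 with the replicate block. It was 0 with the stricter filter, which removes Kcnj15. Leaving out 1 library gave 1 to 10 (wild-type ascending 1), 4 for wild-type descending 5, and 2 for wild-type ascending 3 and 5, wild-type descending 1 and mutant descending 4. For AGT-ASO (10) it was 0 under 0.01, 2 with the limit, 251 with DESeq2, 0 with limma-voom, 147 with no filter, 0 with the brown adipocyte score, 1 with the heart muscle score, 2 with the mitochondrial share and 4 without the libraries that stand apart. Leaving out 1 library gave 0 (AGT-ASO 15, 18 and 19, control 12, 13 and 16) to 180 (control 8), 40 for AGT-ASO 14 and 1 for control 17. The called lists, in the order of the comparisons above, were 0, 0, 3, 3, 0 and 0 with an estimated correlation, and 1, 0, 0 and 0 with fry in the genotype, interaction and AGT-ASO comparisons. With 1 library left out they were 15 to 20, 15 to 25, 11 to 19, 13 to 19, 13 (mutant ascending 2) to 23, and 15 to 25. The genes that rose by genotype had a median with AGT-ASO of -0.2311 with the heart muscle score and -0.1722 for genes called in both regions, both past an unadjusted threshold of 0.05. Its range with 1 library left out was -0.1546 to -0.04149, and -0.2742 to -0.1567 with the score. Those that fell had 0.1961 with the score and 0.09693 without the libraries that stand apart, also past it. Their range was 0.00655 to 0.09056, and 0.1675 to 0.2331 with the score. The mouse as a block ended the calls of Gpr176, Myh7, Fbln7, Col11a2, Lmntd1, Ffar4 and Gpm6a by genotype, and of 3 lists: the elastic fibre list in descending aorta (adjusted p = 0.105), neutrophil and mast cell markers in ascending aorta (0.0681) and fibroblast markers between regions of wild-type mice (0.0663). Other lists passed only with the block. By ascending genotype these were targets of mechanical signalling (adjusted p = 0.047). Between regions of wild-type mice they were the pathway of transforming growth factor beta (0.0131), smooth muscle channels and receptors (0.0151), mechanical signalling (0.041), Wnt and Notch genes (0.0151) and neutrophil and mast cell markers (0.0131). In mutant mice they were mechanical signalling (0.0268), immediate early genes (0.0102), clock genes (0.0341) and erythroid markers (0.0216). In the interaction they were matrix proteases (0.0373), endoplasmic reticulum stress (0.00655), immediate early genes (0.00122) and brown adipocyte markers (0.0275). Depth limits Agt and Agtr2, which the count filter removed.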

Other observations

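The tests of the genes around Kcnj15 and Fbn1, of the sign in both regions, and those with the heart muscle score, were chosen after the results were seen; the splits of the libraries and mice were set out before.

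Lox, the gene of an enzyme that crosslinks collagen and elastin, was highest in mouse 2 in both regions, at 718.5 CPM in ascending and 510.9 CPM in descending aorta. Proteoglycan genes moved both ways in mutant ascending aorta, where 2 of 33 rose and 3 fell (5 and 10 adjusted over the list alone; adjusted p of the list = 0.44). Markers of other tissues also differed by treatment in the antisense libraries at the preset correlation. Schwann cell and neuron markers had a median log2 fold change of -1.03 with AGT-ASO over 11 genes, lymphatic markers -0.73 over 8, white adipocyte markers -0.64 over 15 and erythroid markers 1.17 over 6. Adjusted over the list alone, 8, 3 and 2 members of the first 3 were lower, 1 of the first was higher, and 2 erythroid markers were higher. None of these 4 lists passed with an estimated correlation (adjusted p = 0.38, 0.38, 0.50 and 0.39). Pecam1, an endothelial marker, stood at 685 to 1304 CPM in the means of the untreated groups and at 108 and 115 CPM in the antisense groups, which were separate experiments.

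Genes around Kcnj15 were looked at over 1 Mb on either side. Of 17 tested genes there, 3 were lower in mutant mice in both regions: Kcnj15 and the overlapping models Gm31641 (log2 fold change -2.50 in ascending and -3.09 in descending aorta) and Gm49643. Gm49643 lies on the opposite strand, had a log2 fold change of -1.58 in ascending aorta, and was at least 20.8-fold lower in descending aorta, with 0 counts in all 4 mutant libraries. Another 13 were called in neither region, among them Erg (-0.19 and -0.37), Ets2 and Dyrk1a. Sh3bgr had a log2 fold change of -0.40 in descending aorta (adjusted p = 0.036).

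Tagln, an abundant smooth muscle transcript whose position overlaps Pcsk7 on the opposite strand, stood at 51.6 CPM in wild-type ascending aorta, where Acta2 stood at 11460 CPM.

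DNA beside Fbn1 that was carried along with the mutation may add to the genes called by genotype. Within 20 Mb of Fbn1 lay 4 of the 342 genes of the ascending aorta, where 6.01 would be there by chance (odds ratio 0.66, 95% interval 0.177 to 1.72, Fisher's exact test, p = 0.53), which argues against a 2-fold excess there. Of the 189 genes of the descending aorta 3 lay there, where chance gives 3.32 (odds ratio 0.90, 95% interval 0.183 to 2.70, Fisher's exact test, p = 1). Among these 3 were Gpr176 and Grem1, the largest rise taken by the rule in that region (chromosome 2, 113746164 to 113758646). The test counts positions and does not weigh the size of a change. Of the 83 genes called in both regions 1 did, Gpr176, where chance gives 1.46 (odds ratio 0.68, 95% interval 0.0170 to 3.93, Fisher's exact test, p = 1). The intervals of the last 2 hold both no excess and an excess of more than 2-fold, so the test leaves these open.

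Other splits of the samples were compared with the real one for each count. For descending genotype the real split gave 189 genes and the highest other of 35 gave 2. For regions the numbers were 1741 against 5 in wild-type and 1552 against 106 in mutant mice. In each only 1 split, the real one, gave as many. This argues against chance, but 1 of 35 is the smallest share that these tests can give. That share was not adjusted over the comparisons, so chance is not firmly excluded. The split with 106 sets mice 2 and 4 against 6 and 8 with both regions in each group, and so compares mice, not regions. Among the 8 splits that part all pairs, the highest other was 0 in both genotypes. The number of called lists was not beyond other splits: 27, 8, 31 and 12 of 35 splits gave as many for ascending genotype, descending genotype and regions in wild-type and mutant mice. The highest others there were 25, 27, 30 and 31, and for regions 18 and 19 among splits that part all pairs. With AGT-ASO 16 of 100 splits gave as many lists, and the highest other gave 26.

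The correlation across genes of the genotype fold changes of both regions was 0.399 in fits of the mice by region, and 3 of 35 splits of the 8 mice gave one as high, up to 0.450. Chance cannot be excluded for it, since libraries of 1 mouse share their variation, with a median of 0.275 over other splits. The same holds for the sign of the 342 ascending genes, which was the same in the descending aorta for 93.86%. With the 342 genes of smallest p in the ascending aorta of each split, 2 of 35 splits gave as high a share, with a median of 77.6% over other splits and 94.74% as the highest.

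A hypothesis is that AGT-ASO moves ascending genotype genes the other way and that heart muscle content hides part of it. The median of the genes that rose was as far from 0 in 5 of 126 splits of the antisense libraries, with 0.142 as the highest other. That share is under 0.05 only without adjustment over both sets, and fry did not pass, so chance is not firmly excluded. For the genes that fell it was 50 of 126 splits, with 0.154 as the highest other. With the heart muscle score 1 of 126 splits, the real one, was as far from 0 for each set, with 0.187 and 0.175 as the highest others. This may reflect a shift with treatment, but the score was added after the data were seen. With the score and 1 library left out the medians were -0.2742 to -0.1567 and 0.1675 to 0.2331, -0.1567 and 0.2331 without control library 8. Without the score they were -0.04149 and 0.007442 without control library 8, and -0.08976 and 0.00655 without AGT-ASO library 15.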
